A study of Bos taurus with 30 samples.

How the data were processed

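Gene expression was measured in pools of bovine day 7 blastocysts on 2-colour Agilent arrays of the EmbryoGENE design. Per the labels, 5 groups with 3 replicate pools each were hybridised against blastocysts grown wholly in vivo, and each pool was run on 2 arrays with the dyes exchanged, which gave 30 arrays. The labels' protocols name PicoPure extraction, linear T7 amplification with a RiboAmp kit and Kreatech ULS labelling. The scanner files hold mean spot signals and local backgrounds as intensity values, made with Feature Extraction 10.5.1.1 or 10.7.3.1 per the file headers. The deposited value table holds log2 ratios of group over control, a reading taken from its comparison with the scanner signals, because its scale, centring and direction are not given in the sources used here. Its column medians lay between -0.0342 and 0.0308, and over probes its columns correlated with the ratios computed here at r = 0.994 to 0.999. The base of its logarithm was inferred from a median slope of 1.02 against those ratios, and its normalization method stays unknown.

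Ratios were computed from the scanner files with limma 3.58.1 in R 4.3.3. The background was corrected by normexp with an offset of 50, each array was normalised by loess, and every ratio was turned to group over control. The 1417 control spots were left out after the background correction and had no weight in loess. Another 720 readings marked as outliers were set to missing, and 0 spots of biological probes were saturated. A probe was tested if it was well above background on at least 50% of the arrays of at least 1 of the 6 groups, the control included, in the channel holding that group. This kept 24037 of 43794 probes, or 54.9%. The local backgrounds had medians of 48.0 to 66.0 in green and 68.0 to 88.0 in red, whereas negative control spots had medians of 235 to 953.9 in green and 93.6 to 1537 in red. Normexp on the local background therefore leaves unspecific signal in dim probes, which draws their ratios toward 0.

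The dye-swapped arrays of a pool were averaged and counted as 1 replicate. All 15 replicates were fitted together with lmFit and eBayes, with 1 mean per group, 10 residual degrees of freedom and 13.3 after moderation. Each group was tested against 0, that is against the control in the other channel, and 4 differences between groups were tested as contrasts of the same fit. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the tested probes. Because the control RNA sits in the other channel of every array, comparisons with it may share its pools. The number of arrays limits the precision of every value. On simulated data with the probe variances of these arrays and 24037 probes, the comparison of Vivo 4-cell with the control recovered 58.0% of the probes changed 2-fold and 96.0% of those changed 4-fold. The comparison of IVP with Vivo 4-cell recovered 42.0% and 80.0% of them. Each simulated comparison changed 50 probes per size, in the first group only, with independent noise between pools. Recovery depends on how many probes change and on shared variation, so it may differ in the data.

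The files do not pair the probe identifiers with genes, and the reference table, of assembly ARS-UCD2.0, holds nothing that matches them. All counts are therefore of probes, tested singly. The 21 gene lists fixed before the data were examined could not be tested, nor could the summaries of several probes per gene. The rule for named items took the largest changes in each direction among probes past the threshold, with the same sign on all 6 arrays of the group for comparisons with the control. Since no gene names apply, 2 probes per direction are named in each comparison. A probe that was not well above background on any array of a group has only a bound there. It was computed from single-channel values after loess and Aquantile, as the bright group's mean against the higher of the dim probe's own signal and the lowest signal of probes above background.

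The replicate numbers were checked for pairing before the blocked calls were read. Over probes, the deviations of same-numbered pools from their group means correlated at 0.512, 0.471 and 0.139 between IVP and Vitro 16-cell. They correlated at 0.309, 0.164 and 0.288 between Vivo 4-cell and Vivo 16-cell, at 0.504, 0.168 and 0.37 between IVP and Vivo 4-cell, and at 0.537, 0.521 and 0.546 between IVP and Vivo 16-cell. Between Vitro 16-cell and Vitro 4-cell they were 0.118, 0.421 and -0.0991, so those numbers were not read as pairs. The labels give no source for the pairing of the others.

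The arrays came from 18 slides and were scanned on 7 days that fell into 2 periods, 22 arrays in the first and 8 in the second. The second period holds all Vivo 4-cell arrays and 1 array each of Vitro 4-cell replicates 2 and 3. Alternatives chosen before the data were examined covered the background correction, normalization, detection filter, replicate block, samples in the fit, dye term, array weights, slide, the deposited table and each replicate left out. The fits that use the scanning period or scan day, and the comparison of IVP with Vivo 16-cell, were chosen after seeing the data. Fits with a dye term, the slide, the scanning period or the scan day used single arrays in place of pool means. Those of the dye term and the period held the pool as a random term, with 1 correlation for all probes. Over all arrays it was 0.27 with the dye term and 0.37 with the period as a block. These fits over all arrays have more residual degrees of freedom than that of pool means. Their higher counts are therefore not directly comparable with it. With the slide or scan day as the random block no term joined the 2 arrays of a pool as 1 replicate.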

Results

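The data were log2 ratios of transcript levels in pools of bovine day 7 blastocysts, each against blastocysts that developed wholly in vivo. Vitro 4-cell and Vitro 16-cell embryos were matured, fertilised and cultured in vitro up to those stages and finished development in recipients. Vivo 4-cell and Vivo 16-cell embryos developed in vivo up to those stages and finished in culture. IVP embryos were kept in vitro throughout. Each of the 5 groups had 3 replicate pools and 6 arrays. The share of probes well above background ranged from 32.5% to 67.1% over the arrays in green and from 23.6% to 48.2% in red. The median red signal was 96.6 to 655 on arrays of the first scanning period and 958 to 1914 on those of the second. By group, 50.8% of probes were above background on at least 50% of the arrays in Vitro 4-cell, 36.6% in Vitro 16-cell, 38.1% in IVP, 47.2% in Vivo 4-cell, 39.6% in Vivo 16-cell and 37.3% in the control. No 2 arrays held identical values.

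The dye-swapped arrays of a pool correlated at 0.0447 to 0.669 over probes, and at 0.172 to 0.879 once the mean dye effect of each probe was removed. The lowest of the latter values, 0.172, 0.318 and 0.431, were those of Vitro 4-cell. Probes are not independent replicates in these correlations.

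**Figure D1:**
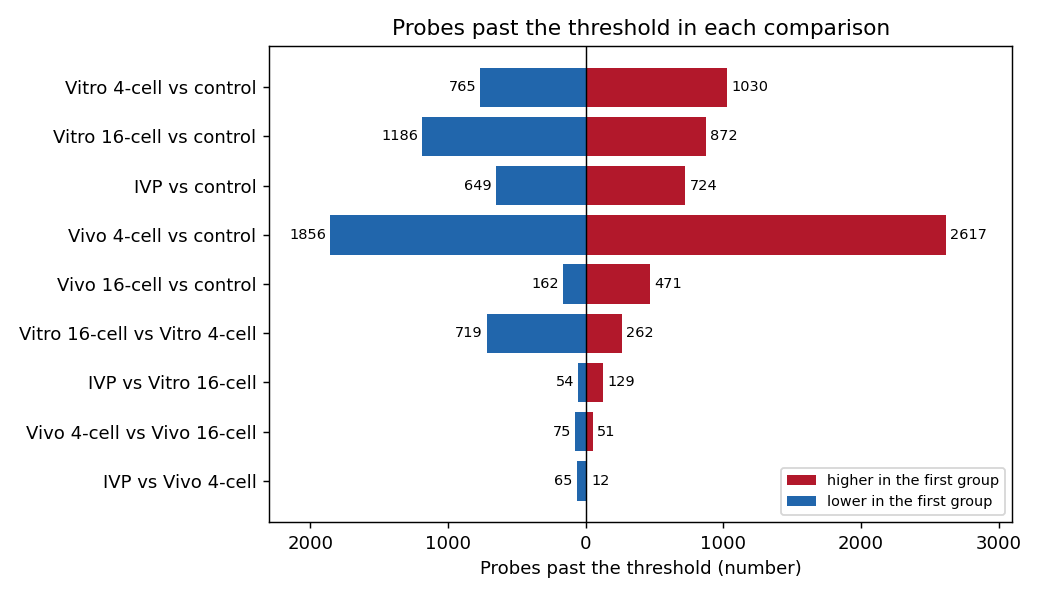
Bars give the number of probes past the threshold in each of the 9 comparisons, higher in the first group to the right and lower to the left. Vivo 4-cell against the control has the longest bars, with 2617 higher and 1856 lower probes.

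Vitro 4-cell blastocysts were compared with the control to address in vitro conditions up to the 4-cell stage. Of 24037 probes, 1795 passed the threshold, 1030 higher and 765 lower, and 596 of them changed at least 2-fold. Probe EMBV3_38850 was higher by 3.13 on the log2 scale (SE 0.61, n = 3, limma adjusted p = 0.0152), and EMBV3_02417 by 3.02 (SE 0.64, adjusted p = 0.0195). EMBV3_18825 fell by 3.50 (SE 0.72, adjusted p = 0.0186) and EMBV3_33336 fell by 2.54 (SE 0.39, adjusted p = 0.00572). All of them had the same sign on 6 of 6 arrays; EMBV3_02417 was above background on 2 of the 6 control channels and EMBV3_18825 on 4 of the 6 group channels. Leaving out replicate 2 left 139 probes and leaving out replicate 3 left 197. In fits of single arrays the count was 1643 in the first scanning period and 6210 in the second, which holds only single arrays of replicates 2 and 3. It was 3202 over both periods without a period term and 1286 with the period as a block. Under that block, which the arrays of replicates 2 and 3 span, EMBV3_38850 was higher by 2.31 (SE 0.52, adjusted p = 0.00728) and EMBV3_18825 fell by 2.76 (SE 0.60, adjusted p = 0.00536). EMBV3_02417 missed the threshold without background correction, at 2.18 (adjusted p = 0.0561). Without loess the higher share was 92.7% in place of 57.4%.

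Vitro 16-cell blastocysts addressed the same question for in vitro conditions up to the 16-cell stage. Here 2058 probes passed, 872 higher and 1186 lower, with 928 changed at least 2-fold. EMBV3_29572 was above background on all 6 arrays of the group and on 0 control channels, and was at least 10.6-fold higher than the control (adjusted p = 0.000435). EMBV3_07099 was higher by 3.41 (SE 0.53, n = 3, adjusted p = 0.00154). EMBV3_25141 fell by 4.02 (SE 0.45, adjusted p = 0.000176), with -4.05, -4.03 and -3.98 in the 3 pools, and was above background on 3 of the group's 6 arrays. EMBV3_35188, above background on 5 of them, fell by 3.85 (SE 0.48, adjusted p = 0.000366). Leaving out replicate 3 left 887 probes and leaving out replicate 2 left 1221. All arrays of this group were scanned in the first period, on a day of their own. In fits of single arrays the count was 3091 without a period term, 3845 in that period alone and 3471 with the period as a block. Without loess the higher share was 21.9% in place of 42.4%.

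IVP blastocysts, kept in vitro throughout, differed from the control in 1373 probes, 724 higher and 649 lower, 467 of them at least 2-fold. EMBV3_02417 was higher by 3.62 (SE 0.64, n = 3, adjusted p = 0.00995) and EMBV3_33905 by 2.89 (SE 0.52, adjusted p = 0.0104); the control was above background on 1 and 4 of 6 channels for them. EMBV3_18825 was above background on 0 of 6 IVP channels and was at least 9.16-fold lower than the control (adjusted p = 0.0187). EMBV3_30571 fell by 2.99 (SE 0.59, adjusted p = 0.0151). The count was 307 without replicate 1, 222 without replicate 2 and 84 without replicate 3. In fits of single arrays the count was 3088 without a period term and 3510 with the period as a block. Within the first period, which holds all arrays of the group, it was 3996. The higher share of 52.7% was 88.6% without loess and 32.5%, or 276 of 849, among probes above background in both channels on all arrays.

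Vivo 4-cell blastocysts, moved to culture at the 4-cell stage, differed from the control in 4473 probes, 2617 higher and 1856 lower. Of these, 1712 changed at least 2-fold. EMBV3_38850 was higher by 5.67 (SE 0.61, n = 3, adjusted p = 0.000643) and EMBV3_02417 by 4.89 (SE 0.64, adjusted p = 0.00125). In the control these were above background on 5 and 1 of 6 channels. EMBV3_18825, above background on 2 of 6 group channels, fell by 5.24 (SE 0.72, adjusted p = 0.00153). EMBV3_17133 was above background on 0 of 6 channels of the group and at least 6.64-fold lower (adjusted p = 0.016). The pools had an SD of 1.54 for EMBV3_38850. With only this group in the fit the count was 0 (limma, 6443 at an unadjusted p under 0.05) and the 4 named probes had an adjusted p of 0.0962. All arrays of this group belong to the second scanning period. In fits of single arrays the count was 3079 within it and 1523 with the period as a block. The higher share under that block was 43.6%, against 58.5% in the fit of pool means. Under that block EMBV3_38850 was higher by 3.21 (SE 0.84) and EMBV3_02417 by 3.87 (SE 0.83), while EMBV3_18825 fell by 3.02 (SE 0.98, adjusted p = 0.0608). EMBV3_17133 was then at -1.93 (SE 1.23, adjusted p = 0.426), a smaller fall than its bound. Without replicate 3 the count was 550 and without replicate 2 it was 2696. With Agilent's processed signals the higher share was 69.7%, without loess 89.2%, and among probes above background in both channels on all arrays 38.5%, or 730 of 1896.

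Vivo 16-cell blastocysts, moved to culture at the 16-cell stage, differed from the control in 633 probes, 471 higher and 162 lower, with 242 at least 2-fold. EMBV3_02417, above background on 2 of 6 control channels, was higher by 3.80 (SE 0.64, n = 3, adjusted p = 0.0116) and EMBV3_07099 by 3.65 (SE 0.53, adjusted p = 0.0065). EMBV3_35188 fell by 2.45 (SE 0.48, adjusted p = 0.0204) and EMBV3_03595 fell by 2.25 (SE 0.46, adjusted p = 0.0224). EMBV3_35188 missed the threshold with scale normalization, at -2.41 (adjusted p = 0.0672), with the authors' deposited values, at -2.42 (adjusted p = 0.0659), and without loess, at -2.02 (adjusted p = 0.088). The count was 24 without replicate 1, 119 without replicate 2 and 117 without replicate 3. In fits of single arrays the count was 1494 without a period term and 1770 with the period as a block. Within the first period, which holds all arrays of the group, it was 2243. Without loess the higher share was 96.1% in place of 74.4%.

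**Figure D2:**
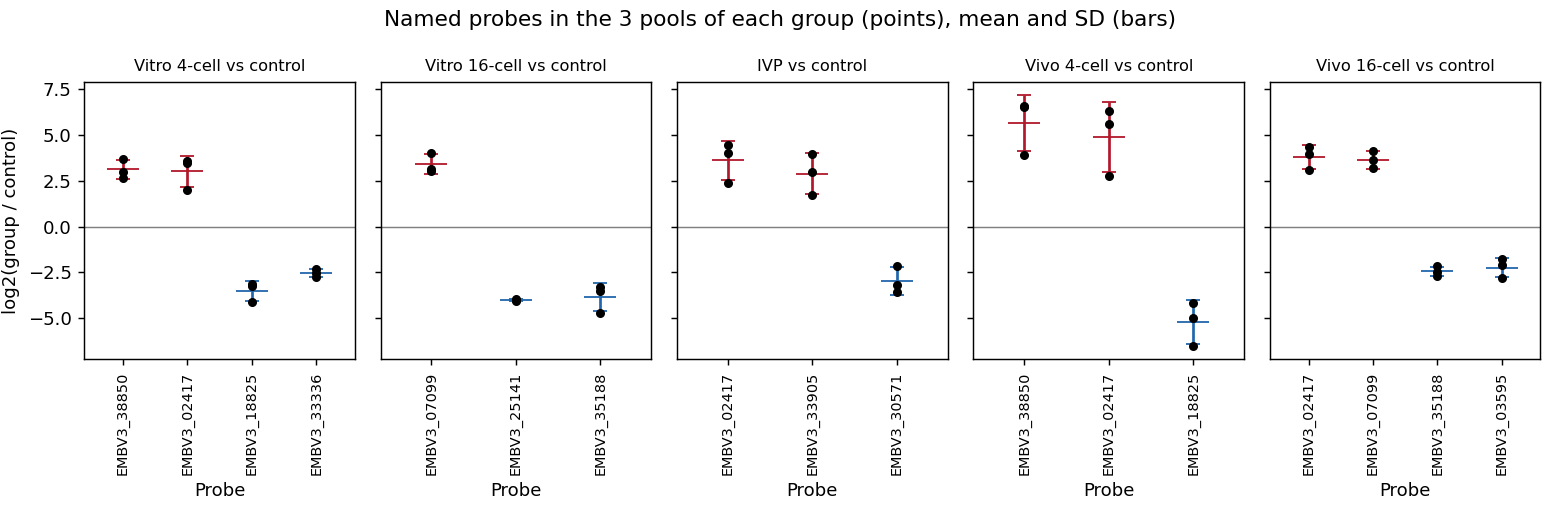
Points give the measured log2(group / control) in the 3 pools of a group for each named probe that has more than a bound, and bars the mean and SD. EMBV3_38850 in Vivo 4-cell has the highest mean, 5.67, and EMBV3_18825 in the same group the lowest, -5.24.

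The sizes depended on the processing. Over the 32 named values of all comparisons that have more than a bound, the folds without background correction were a median of 0.807 times those given here, with a range of 0.418 to 0.95 times. Median centring without loess gave 0.46 to 2.29 times, array weights 0.56 to 1.30 times and the period as a block 0.0871 to 1 times. Agilent's processed signals with median centring, which change both steps, gave a median of 1.36 and a range of 0.902 to 5.93 times, and EMBV3_02417 in Vivo 4-cell was then higher than the control by 7.21 on the log2 scale.

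Several probes were called in more than 1 of these comparisons. In the same direction, 2034 probes passed in at least 2 comparisons, and 75 in all 5, of which 63 were higher and 12 lower. Leaving out 1 replicate moved the 2034 to between 1101 and 2564. Another tally, of probes called higher in 1 comparison and lower in another, was 362. EMBV3_38850 and EMBV3_07099 were higher in all 5. Vitro 4-cell and Vivo 4-cell shared 616 higher and 471 lower probes, against 112.1 and 59.1 for independent lists. They are the groups with arrays of the second scanning period, which holds arrays of number 2 and 3 of both. Pools of these numbers correlated at 0.698 and 0.697 between the groups, and those of number 1 at 0.362. IVP and Vivo 16-cell shared 189 higher and 74 lower probes, against 14.2 and 4.37. Vitro 16-cell and Vivo 4-cell were called in opposite directions in 321 probes and together in 215 higher and 78 lower, against 94.9 and 91.6. Simulated unchanged groups on shared control pools gave 0 shared calls in each pair, which sets no level for lists that hold real changes. The fitted ratios of Vitro 4-cell and IVP had a covariance of 0.134 over probes against 0.0131 simulated, and those of Vitro 16-cell and Vivo 4-cell -0.0232 against 0.0131. The controls could not be split into parts of 2 pools, so part of the excess may come from shared controls.

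**Figure D3:**
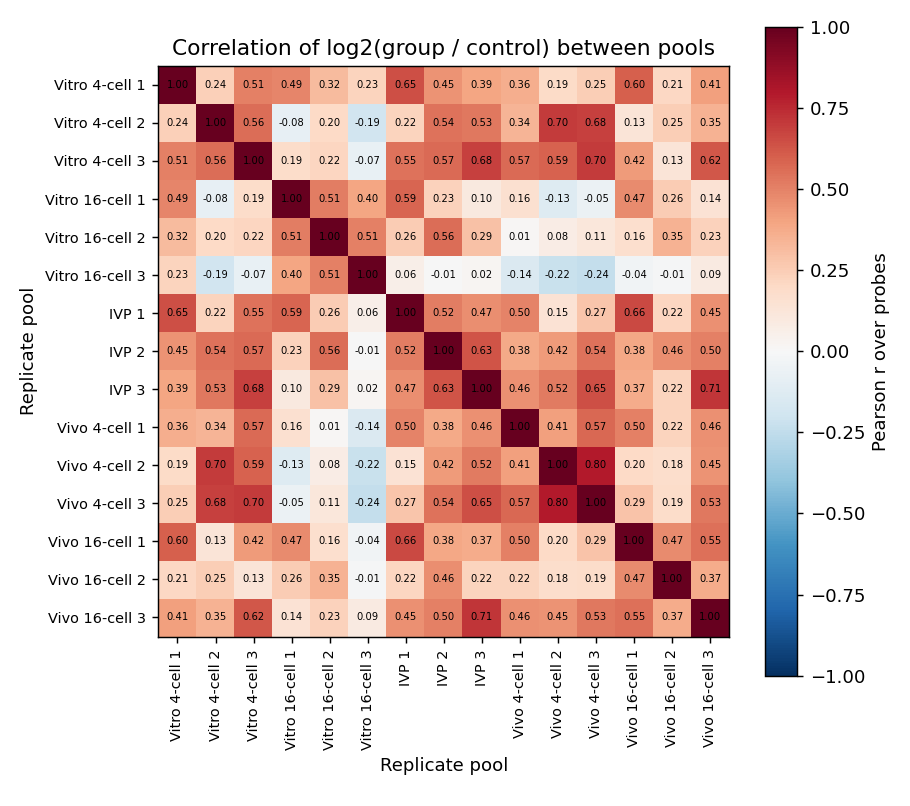
Each cell gives the Pearson correlation, over probes, of log2(group / control) between 2 of the 15 pools. Vitro 16-cell pools correlated with each other at a mean of 0.472 and with differently numbered pools of the other groups at a mean of 0.0805.

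Vitro 16-cell was compared with Vitro 4-cell to address the window from 4 to 16 cells after an in vitro start. These groups shared no scan day or slide with each other or with another group. The culture window therefore cannot be told apart from the scan day and slide here. In this contrast 981 probes passed, 262 higher and 719 lower. EMBV3_23715 was higher by 2.69 (SE 0.55, n = 3 per group, adjusted p = 0.0219) and EMBV3_23077 by 2.59 (SE 0.56, adjusted p = 0.0288). EMBV3_11161 fell by 3.52 (SE 0.53, adjusted p = 0.00813) and EMBV3_28137 fell by 3.43 (SE 0.43, adjusted p = 0.00338). The ratio of EMBV3_11161 to the control was -3.05 in Vitro 16-cell and 0.47 in Vitro 4-cell. Leaving out Vitro 4-cell replicates 1, 2 and 3 gave 2532, 70 and 261 probes, and leaving out Vitro 16-cell replicates 1 and 3 gave 645 and 176. In fits of single arrays the count was 2458 without a period term, 993 in the first period and 713 with the period as a block. Under that block EMBV3_28137 fell by 2.47 (SE 0.35, adjusted p = 0.000144) and EMBV3_23077 was higher by 1.93 (SE 0.41, adjusted p = 0.00866). For 253 of the 981 probes the control channels differed more between the groups than the group channels did. EMBV3_23077 missed the threshold without loess, at 1.47 (adjusted p = 0.0704), and EMBV3_23715 with array weights, at 1.86 (adjusted p = 0.053). The higher share was 26.7%, against 39.1% with Agilent's processed signals, 4.38% without loess and 45.1% among probes above background on all arrays.

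IVP was compared with Vitro 16-cell for the time after the 16-cell stage on an in vitro start. These groups also shared no scan day or slide. Here 183 probes passed, 129 higher and 54 lower, and the replicate block raised this to 1381. EMBV3_11161 was higher by 2.87 (SE 0.53, n = 3 per group, adjusted p = 0.0326). EMBV3_19872 was above background on 0 of 6 Vitro 16-cell channels and at least 5.49-fold higher in IVP (adjusted p = 0.00583). EMBV3_41427 fell by 2.50 (SE 0.41, adjusted p = 0.0267) and EMBV3_17388 fell by 2.44 (SE 0.49, adjusted p = 0.0418). For 2 of the 183 probes the control channels differed more between the groups than the group channels did. The count was 17, 16 and 14 without IVP replicates 1, 2 and 3, and 14 without Vitro 16-cell replicate 3. In fits of single arrays the count was 1563 without a period term, 2964 in the first period and 2341 with the period as a block. The higher share of 70.5% was 95.6% without loess and 52.2% among probes above background on all arrays.

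Vivo 4-cell was compared with Vivo 16-cell for the window from 4 to 16 cells on an in vivo start. In all, 126 probes passed, 51 higher and 75 lower, and 1480 with the replicate block. EMBV3_02399, above background on 2 of 6 Vivo 16-cell channels, was higher by 2.39 (SE 0.34, n = 3 per group, adjusted p = 0.0234), and EMBV3_19202 by 2.27 (SE 0.42, adjusted p = 0.0366). EMBV3_32328 fell by 3.74 (SE 0.60, adjusted p = 0.0253) and EMBV3_00884 fell by 2.86 (SE 0.42, adjusted p = 0.0234). For 103 of the 126 probes the control channels differed more between the groups than the group channels did. The group channels differed by 0.54 and the control channels by -1.73 for EMBV3_19202, and by -0.57 and 2.29 for EMBV3_00884. With Agilent's processed signals EMBV3_02399 was higher by 4.95 and EMBV3_32328 fell by 6.19. The groups lie in different scanning periods. In fits of single arrays the count was 491 without a period term. It was 343 with the period as a block, which rests on Vitro 4-cell alone. None of the 4 named probes passed under that block: EMBV3_02399 was 0.98 (SE 0.44), EMBV3_19202 turned to -0.44 (SE 0.42), EMBV3_32328 was -1.69 (SE 0.65) and EMBV3_00884 was -0.68 (SE 0.45), with adjusted p from 0.237 to 0.729. Leaving out Vivo 4-cell replicates 1, 2 and 3 gave 1311, 22 and 1, and leaving out Vivo 16-cell replicates 1, 2 and 3 gave 0, 0 and 1, with limma counts of 2786 and 2648 at an unadjusted p under 0.05 for both zeros.

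IVP was compared with Vivo 4-cell for the time up to the 4-cell stage when the rest was in vitro. Only 77 probes passed, 12 higher and 65 lower. With the replicate block 596 passed, 225 higher and 371 lower. EMBV3_00884 was higher by 2.26 (SE 0.42, n = 3 per group, adjusted p = 0.0478) and EMBV3_12298 by 2.15 (SE 0.36, adjusted p = 0.0351). EMBV3_25141 fell by 3.97 (SE 0.64, adjusted p = 0.0351) and EMBV3_15805 fell by 3.08 (SE 0.57, adjusted p = 0.0486). For 59 of the 77 probes the control channels differed more between the groups than the group channels did. The group channels differed by -0.89 and the control channels by 3.08 for EMBV3_25141, by -0.44 and 2.63 for EMBV3_15805, by 0.34 and -1.92 for EMBV3_00884 and by 0.21 and -1.94 for EMBV3_12298. These groups also lie in different periods. The higher share was 15.6% in the fit of pool means. In fits of single arrays the count was 298 without a period term, with a higher share of 32.55%. It was 476 with the period as a block, with a higher share of 58.0%. None of the 4 named probes passed under that block: EMBV3_00884 was 0.08 (SE 0.45), EMBV3_12298 was 0.53 (SE 0.40), EMBV3_25141 was -0.45 (SE 0.65) and EMBV3_15805 was -0.39 (SE 0.54), with adjusted p from 0.611 to 0.98. Leaving out IVP replicates 1, 2 and 3 gave 0, 0 and 1, and leaving out Vivo 4-cell replicates 1, 2 and 3 gave 392, 0 and 0; limma counts at an unadjusted p under 0.05 were 2067, 2318, 2235 and 1851 for the zeros. Scale normalization gave a higher share of 29.2%, and probes above background on all arrays one of 34.9%.

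The spread behind every test came from all 15 pools. With only the groups compared in the fit, 21 of the 36 named calls were lost. They were 1 of 4 in Vitro 4-cell (EMBV3_02417, adjusted p = 0.0571), all 4 in IVP (0.0562 to 0.0964) and all 4 in Vivo 4-cell, and 0 in Vitro 16-cell and in Vivo 16-cell. Of the differences between groups, 3 of 4 were lost for Vitro 16-cell against Vitro 4-cell (0.0556 to 0.109) and all 4 for IVP against Vitro 16-cell (0.0607 to 0.112). For Vivo 4-cell against Vivo 16-cell 2 of 4 were lost (0.0622 and 0.0931), and for IVP against Vivo 4-cell 3 of 4 (0.127 to 0.168). In limma the counts of probes were 0 for IVP, Vivo 4-cell, and IVP against Vitro 16-cell, with 6304, 6443 and 4609 at an unadjusted p under 0.05. Without loess, all 4 named calls of each of the last 2 contrasts were lost, and those of IVP against Vivo 4-cell also without the detection filter (0.0507 to 0.0663) and with the scan day as a random block (0.0826 to 0.125). In that contrast 2 of 4 were lost without background correction (0.0654 and 0.0877), with Agilent's processed signals (0.0578 and 0.0651), with scale normalization (0.0579 and 0.0614) and with the authors' deposited values (0.0582 and 0.0592). EMBV3_19202 in Vivo 4-cell against Vivo 16-cell was lost with Agilent's processed signals (0.0514), without the detection filter (0.0517) and with the scan day (0.0926). Single calls were also lost for EMBV3_17133 in Vivo 4-cell without background correction (0.0558) and EMBV3_17388 in IVP against Vitro 16-cell without the detection filter (0.0598).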

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

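The tests of the scanning period, of the control RNA and control channels, of the scan day and of splits within pairs, and the blocked fits of the windows, were chosen after the results were seen; the others were set before. The effect of 1 culture window was set against itself in embryos with another history. For the window from 4 to 16 cells, 3028 probes differed between the in vivo and the in vitro start, 1702 higher and 1326 lower after the in vivo start. With arrays fitted singly and a dye term the count was 4359, and with the scanning period added it was 97. Of 100 splits of the same pools, the others of which were a random draw, 1, the real one, gave as many. The highest other gave 2056. The labels do not say whether the numbers pair the Vivo pools. Of the 80 splits that part all same-numbered Vivo pools 1, the real one, gave as many, with 654 as the highest other. With the replicate block the counts were 5248 and 1274. The splits argue against labels without effect in either start as the source of the count. They do not tell which start carries it, and the scanning period was not excluded. The difference only turns its sign when all labels of the 2 starts are exchanged. In that sense the split with 2056 keeps the Vitro labels and exchanges only 1 pool each way between the Vivo groups. It keeps most of the real labels, but that alone does not account for its count. The other drawn splits that keep the Vitro labels and exchange 1 Vivo pool each way gave 46, 46, 3 and 0. Other structure among the samples therefore stays open.

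For the window up to 4 cells, 558 probes differed between later culture in vitro and in vivo, 1563 with arrays fitted singly and 183 with the period added. For the window after 16 cells, 60 differed between starts, 533 with arrays fitted singly and 803 with the period added. In each, 2 of 20 splits gave as many, and 20 are too few for a share under 0.05. With the replicate block they were 2664 and 399, and 8 splits that part all pairs are again too few. Every split moves pools between 2 groups only. It keeps the ratio of the remaining group, Vitro 4-cell or Vivo 16-cell, to the control in the difference. These ratios alone gave 1795 and 633 calls, so high counts can arise in the splits from them. The splits therefore decide nothing for either window. The highest others were 1895, from exchanging IVP replicate 3 with Vivo 4-cell replicate 1, and 1467, from exchanging all labels of IVP and Vitro 16-cell.

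Vivo 4-cell called the most probes of the comparisons with the control, 4473. Detection of more probes in brighter scans was argued against as the whole reason. Among probes above background in both channels on all arrays Vivo 4-cell called 1896, against at most 1060 in any other group. That filter evens out detection but not the brightness of the scans, so an effect of brightness on the ratios stays open. The scanning period stays open, since the shift between periods in the same Vitro 4-cell pools, with dyes balanced, correlated over probes with the Vivo 4-cell ratios at 0.606, against 0.101 for IVP, -0.0277 for Vivo 16-cell and -0.335 for Vitro 16-cell. Another control RNA in the second period stays open as well: the control channel carried a share of 1.15 of the variance of that shift and the group channel -0.153, but an effect of the period on 1 channel more than the other could give this too. The group channel of the same pools also shifted, with an SD of 0.818 over probes against 1.21 in the control channel. The shifts of the 2 channels correlated at 0.769, so the change between periods was not confined to the control channel. Vivo 4-cell no longer called the most with the period as a block (1523, against 3510 for IVP, 3471 for Vitro 16-cell and 1770 for Vivo 16-cell). That block rests on Vitro 4-cell arrays and makes Vivo 4-cell less precise. Under it the SE of EMBV3_02417 was 0.83 in Vivo 4-cell and 0.45 in IVP and in Vivo 16-cell, each 0.64 in the fit of pool means. The lower count may therefore reflect precision. Nor did Vivo 4-cell call the most with the scan day as a random block (2006, against 2685 for Vitro 4-cell), where the 2 arrays of a pool count as separate replicates. Within the second period it called 3079, against 6210 for Vitro 4-cell, which has only single arrays of replicates 2 and 3 there, without a dye swap. With each group fitted alone it called 0, against 1141 for Vivo 16-cell. The order of the groups is therefore not settled.

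Vitro 16-cell ratios were least like those of the other groups. Another control RNA was argued against, because control channels of the same number correlated at a mean of 0.545 between this group and the others of the first period, against 0.215 for different numbers. The scan day stays open, since 1 group was scanned on that day, and the day and the group cannot be told apart. The culture history of the group stays open as well, untested.

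Same-numbered pools of different groups deviated together. Shared control pools are a candidate explanation: in the first period, control channels of the same number correlated by 0.219 and 0.886 more than those of different numbers in the 2 dyes, a mean of 0.552. Centred over the arrays of both periods, these differences were 0.187 and 0.397. Paired embryo pools stay open, since group channels of the same number correlated by 0.169 and 0.259 more, a mean of 0.214 that lies with the dyes on both sides of the 0.2 set beforehand, against 0.709 for the control channels of the same arrays. Both channels share an array, which may carry part of the smaller value.

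Splits of the replicates were too few for a share under 0.05 in each comparison of the report, where 1 split, the real one, reached the count. With 4 sign changes, the real and the highest other counts were 1795 and 0 for Vitro 4-cell, 2058 and 0 for Vitro 16-cell, 1373 and 1 for IVP, 4473 and 0 for Vivo 4-cell, and 633 and 0 for Vivo 16-cell. With 10 splits they were 981 and 0 for Vitro 16-cell against Vitro 4-cell, 183 and 0 for IVP against Vitro 16-cell, 126 and 7 for Vivo 4-cell against Vivo 16-cell, and 77 and 0 for IVP against Vivo 4-cell. In these last 3, where the numbers may pair the pools, 4 splits part all 3 same-numbered pairs. The highest other of them gave 0 with and without the replicate block. The 7 came from a split that parts fewer pairs.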

How the results depend on the processing

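The scanning period and scan day fits and the blocked fits of culture windows were chosen after the data were seen; the other settings were planned. Counts are of probes past the threshold and are given where they moved by over 1.5 times; the cause was not tested except where stated. Aquantile gave the same counts by construction, since it leaves ratios as they are. Without background correction IVP against Vitro 16-cell gave 477. Agilent's processed signals gave 2303 for IVP against the control, 520 for IVP against Vitro 16-cell, 31 for Vivo 4-cell against Vivo 16-cell and 25 for IVP against Vivo 4-cell. Scale normalization gave 456 for IVP against Vitro 16-cell and 342 for Vivo 4-cell against Vivo 16-cell, and the authors' deposited values gave 438 and 341. Median centring without loess gave 4483, 1297, 2747 and 1146 for Vitro 4-cell, Vitro 16-cell, IVP and Vivo 16-cell against the control. It gave 4224 for Vitro 16-cell against Vitro 4-cell, 1868 for IVP against Vitro 16-cell, 0 for Vivo 4-cell against Vivo 16-cell and 0 for IVP against Vivo 4-cell (limma, 2302 and 1744 at an unadjusted p under 0.05), and 4028 probes shared by at least 2 comparisons. No detection filter gave 1188 for Vitro 4-cell against the control, 553 for Vitro 16-cell against Vitro 4-cell, 71 for Vivo 4-cell against Vivo 16-cell and 14 for IVP against Vivo 4-cell. Depth limits the strict filter, which left 6152 probes above background everywhere and so fewer tests. It gave 1013, 1060, 849, 1896 and 206 for Vitro 4-cell, Vitro 16-cell, IVP, Vivo 4-cell and Vivo 16-cell against the control, 194 for Vivo 4-cell against Vivo 16-cell, 43 for IVP against Vivo 4-cell and 1119 shared.

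The replicate block gave 4011, 3345, 3291 and 1621 for Vitro 4-cell, Vitro 16-cell, IVP and Vivo 16-cell against the control. It gave 3043 for Vitro 16-cell against Vitro 4-cell, 1381 for IVP against Vitro 16-cell, 1480 for Vivo 4-cell against Vivo 16-cell, 596 for IVP against Vivo 4-cell and 4522 shared; Vivo 4-cell against the control gave 6598, within 1.5 times. Against the control, this block would also take out variation between control pools if these are shared by number. Fitting only the groups compared, with fewer samples behind the spread, gave 6, 576, 0, 0 and 1141 against the control in the order Vitro 4-cell, Vitro 16-cell, IVP, Vivo 4-cell and Vivo 16-cell, and 20, 0, 18 and 4 for the contrasts in the order of the report. The zeros had limma counts of 6304, 6443 and 4609 at an unadjusted p under 0.05. Arrays with a dye term gave 3202, 3091, 3088 and 1494 for Vitro 4-cell, Vitro 16-cell, IVP and Vivo 16-cell against the control, 2458, 1563, 491 and 298 for the contrasts, and 3882 shared. Array weights gave 4261, 4446, 7288 and 2742 for Vitro 16-cell, IVP, Vivo 4-cell and Vivo 16-cell against the control, 1553, 2483 and 1531 for the last 3 contrasts, and 4500 shared. The slide as a random block was fitted to single arrays with no term for the pool. It gave 4197 and 2010 for Vitro 4-cell and Vivo 16-cell against the control. For the first 3 contrasts it gave 2252, 560 and 486, and 3447 were shared. An adjusted p under 0.01 left 250 shared.

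The first scanning period alone gave 3845, 3996 and 2243 for Vitro 16-cell, IVP and Vivo 16-cell against the control and 2964 for IVP against Vitro 16-cell, and the second gave 6210 for Vitro 4-cell. The period as a block gave 3471, 3510, 1523 and 1770 for Vitro 16-cell, IVP, Vivo 4-cell and Vivo 16-cell against the control, and 2341, 343 and 476 for the last 3 contrasts. All period fits used single arrays. The fit of single arrays without a period gave 3091, 3088 and 1494 for Vitro 16-cell, IVP and Vivo 16-cell. For the last 3 contrasts it gave 1563, 491 and 298. Against that fit the block lowered Vitro 4-cell from 3202 to 1286 and Vitro 16-cell against Vitro 4-cell from 2458 to 713. Under the period block EMBV3_19202 in Vivo 4-cell against Vivo 16-cell turned to -0.439 and 9 other named calls were lost, all in comparisons with Vivo 4-cell. The lowest fold was 0.0871 times that given, for EMBV3_25141 in IVP against Vivo 4-cell. The scan day as a random block, again with no term for the pool, gave 1018 and 2006 for Vitro 16-cell and Vivo 4-cell against the control. For the contrasts it gave 440, 100, 31 and 4. Leaving out 1 replicate gave 139 to 2505 for Vitro 4-cell, 887 to 1508 for Vitro 16-cell, 84 to 307 for IVP, 550 to 4785 for Vivo 4-cell and 24 to 119 for Vivo 16-cell. It gave 70 to 2532, 14 to 195, 0 to 1311 and 0 to 392 for the contrasts, with the unadjusted counts beside the zeros in the report, and 1101 to 2564 shared. Of the 36 named calls, 21 were lost with only the groups compared in the fit, 10 without loess, 6 without the detection filter, 5 with the scan day, 4 without background correction, 3 each with Agilent's signals, scale normalization and the deposited table, and 1 with array weights. Of 156 named values, 69 kept their call without 1 replicate and 87 lost it, and 0 turned direction. Brightest or mean probe per gene and the gene list tests were not run, since the probes have no gene names here.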

Other observations

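The contrast in the first paragraph, its blocked fit and the choice of its groups came after the data were seen. IVP and Vivo 16-cell were scanned on the same days and partly on the same slides. They differed in 4 probes by limma, 0 higher and 4 lower in IVP, with 1207 at an unadjusted p under 0.05. With the replicate block they differed in 7, 0 higher and 7 lower. The 10 splits of these pools are too few for a share under 0.05; the real count was 4, the highest other 0, and 1 split reached it. Among the 4 splits that part all 3 pairs the highest other was also 0, with and without the block.

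A hypothesis was that pools of a group resemble each other beyond their numbers. In the 3 groups scanned wholly in the first period, the mean correlation over probes between differently numbered pools was higher within groups than between them by 0.28. Relabelling the groups within numbers gave as much in 1 of 36 cases (exact one-sided permutation p = 0.0278, the smallest possible), and the next highest difference was 0.2. Scan day may contribute to this for Vitro 16-cell, which had a day of its own. Slides may contribute as well and were not tested here. Differently numbered pools shared slides on all IVP arrays and on most Vitro 16-cell arrays, but not within Vivo 16-cell.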
